A study of Homo sapiens with 6 samples.

How the data were processed

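Pools of synthetic human miRNAs, short RNAs that in cells guide the silencing of messenger RNAs, were held on 3 plates. The plates were combined at 6 sets of masses, and each mix gave 1 small RNA library, made with the NEBNext small RNA kit and sequenced on an Illumina HiSeq with single reads of 50 nt, per the labels' protocols. A mix is named by the ng of plates 1, 2 and 3, so mix_10_1_0.1 held 10, 1 and 0.1 ng. With 1 library per mix there is no replicate of any mix.

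Cutadapt 1.6 and Bowtie 1.0.1 are named in the submitters' processing notes, with no role given. The genome build and the release of the miRNA collection are not given in the sources used here. The deposited data are 10 tables of the whole series. The deposited counts are whole reads: the exact-match tables give counts per miRNA, and 2 further tables give counts of reads by length and by number of mismatches. In 6 of the 8 miRNA tables the authors deposited a score, in which a read weighs 1 when exact and 0.8, 0.6 or 0.4 with 1, 2 or 3 mismatches. These weights were read from the values: differences between successive tables were whole multiples of the weights to within 0.0001, and the sums equalled the deposited read numbers. Whole reads were recovered from them. Tables came as single assignment, with each read at 1 name, and multiple assignment, with a read at each name it matches.

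The plate of each miRNA is not in the tables used here. It was set from mix_10_1_0.1 against mix_0.1_1_10, by the log2 ratio of counts per library total (CPM) with 0.5 reads added. Each miRNA with at least 10 reads over the pair went to the nearest of the 3 mass ratios. The other 4 libraries then tested the response. Per plate, edgeR 4.0.16 (R 4.3.3, limma 3.58.1) fitted a quasi-likelihood model of counts on the log2 share of the plate in the input mass, with the log of total miRNA counts as offset and 2 residual degrees of freedom. The slope was tested against 0 and, with the share in the offset, against 1, two-sided, with Benjamini-Hochberg adjustment over all tested miRNAs at 0.05. A slope of 1 means reads in proportion to input share. The tests measure the spread of single libraries about a line, which may be technical.

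The fit was tested on simulated data for the 293 miRNAs in 20 simulations. A true slope of 1 was called against 0 in 96.1% of miRNAs and a true slope of 0 in 1.56%. Against 1, a true slope of 0.5 was called in 67.2%, 1.5 in 65.3% and 1 in 1.88%. Each miRNA was drawn independently about a mean set by mass share. Shifts shared by all miRNAs of a plate in a library were not simulated, so these rates do not cover them.

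Library pairs that differ in plate mass were compared by the median log2 ratio over the miRNAs of a plate, with no test. Its percentile among 10000 random lists matched on mean reads, drawn from the miRNAs of all 3 plates, is given beside it. Read shares carry exact 95% binomial intervals, and a name with 0 reads has a floor of 3 reads. PCR reads are not independent molecules, so intervals and floors cover counting error only. A predicted read share was computed from the reads per ng of each plate in mix_10_10_10.

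Reads per library after trimming ran from 7492693 in mix_10_1_0.1 to 36654192 in mix_10_10_10, and exact single-assigned reads from 3421405 to 16395453. The floor of 3 reads is 0.183 CPM in mix_10_10_10 and 0.877 CPM in mix_10_1_0.1.

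Named miRNAs followed a rule set before the data were examined. Per plate it took the 3 with most and fewest reads in mix_10_10_10, and the 2 steepest and shallowest slopes past the test against 1. It further took the 10 with most reads added at 1 mismatch, the 10 with most reads at 2 mismatches among names under 10 exact reads, and the 10 gaining most by multiple assignment. Up to 4 members of each of 19 lists, matched on names of either arm, were added. Other miRNAs named were chosen after their values were seen.

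Alternatives set in advance were the other assigning pair, all 6 libraries, TMM and DESeq2 (1.42.0) size factors, the DESeq2 Wald test against 0, read minimums of 1 and 100, log2 ng as covariate, a boundary margin, mismatches, multiple assignment, 0.1 or 1 reads added, and each library left out. Further alternatives were added after seeing the data. Hairpin positions come from GENCODE release 29 on GRCh38, which need not be the authors' build. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.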

Results

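The 6 libraries measured synthetic human miRNAs from 3 plates, mixed at 10, 1 or 0.1 ng per plate. Exact miRNA reads made up between 44.2% of reads, in mix_10_10_1, and 46.4%, in mix_1_0.1_10. With up to 3 mismatches the share was 80.6% to 83.4%. The most common read length was 22 nt in each library. A plate was set for 293 miRNAs, of which 98 fell on plate 1, 98 on plate 2 and 97 on plate 3. Another 55 names with an exact read had under 10 reads over the assigning pair. They include miR-199b-3p, with 28662 exact reads in mix_10_10_10. The other assigning pair gave the same plate to 269 of the 290 miRNAs it could place.

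Whether reads follow the mass put in was asked of the 4 libraries that did not set the plates. The slope on log2 input share was above 0 for 283 of the 293 miRNAs and below 0 for 0 (edgeR quasi-likelihood, adjusted p under the threshold of 0.05). Median slopes were 1.13 on plate 1 (SD over miRNAs 0.33), 1.07 on plate 2 (SD 0.27) and 0.83 on plate 3 (SD 0.20). In the fitted libraries plate 1 was at 10 ng except in mix_1_0.1_10, at 1 ng. The low end of its range thus rests on that library. The median SE was 0.25 on plate 1, 0.11 on plate 2 and 0.13 on plate 3. Against a slope of 1, 35 miRNAs differed, 13 steeper and 22 shallower, and 18 of the shallower ones lay on plate 3. The count of rising miRNAs was 174 with TMM factors and 171 with DESeq2 size factors, and with TMM factors the plate 1 median fell to 0.14. On plate 1, 20 of 98 rose with TMM factors and 2 of 98 with DESeq2 size factors, and the slope was below 0 for 1 and 4 miRNAs over all plates. Both kinds of factor take most miRNAs as level between libraries, while here whole plates change in mass by design. These fits therefore do not decide whether reads follow the share of total mass. The count off a slope of 1 ranged from 2, with the other assigning pair, to 145, with up to 3 mismatches, and was 43 in the DESeq2 Wald test. With the other pair 0 miRNAs were steeper than 1, so the calls steeper than 1 named below did not hold there. The other pair changes both the plates and the libraries fitted, and name blocks, which change the plates alone, left 26. On plate 3 the number of miRNAs shallower than 1 varied more than the median slope. It was 42 with all 6 libraries (median slope 0.84) and 16 to 44 when 1 of these was left out, 18 with name blocks (0.83), 1 with the other assigning pair (0.85, SD over miRNAs 0.13) and 0 on log2 ng (0.80). The median SE on log2 ng was 0.26, against 0.13 in the main analysis. With the predicted share the count was 1 and the median 0.98. Over all plates that fit left 1 steeper, on plate 1, and 7 shallower, with medians of 0.95 on plate 1 and 0.98 on plate 2. Calls steeper than 1 on plates 2 and 3 named below did not hold there. That share comes from a library in the fit. Plates differed in reads per ng, so a slope off 1 on mass share need not mean that reads per ng changed. With TMM factors 15 plate 3 miRNAs were steeper and 0 shallower (median 1.51).

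**Figure D1:**
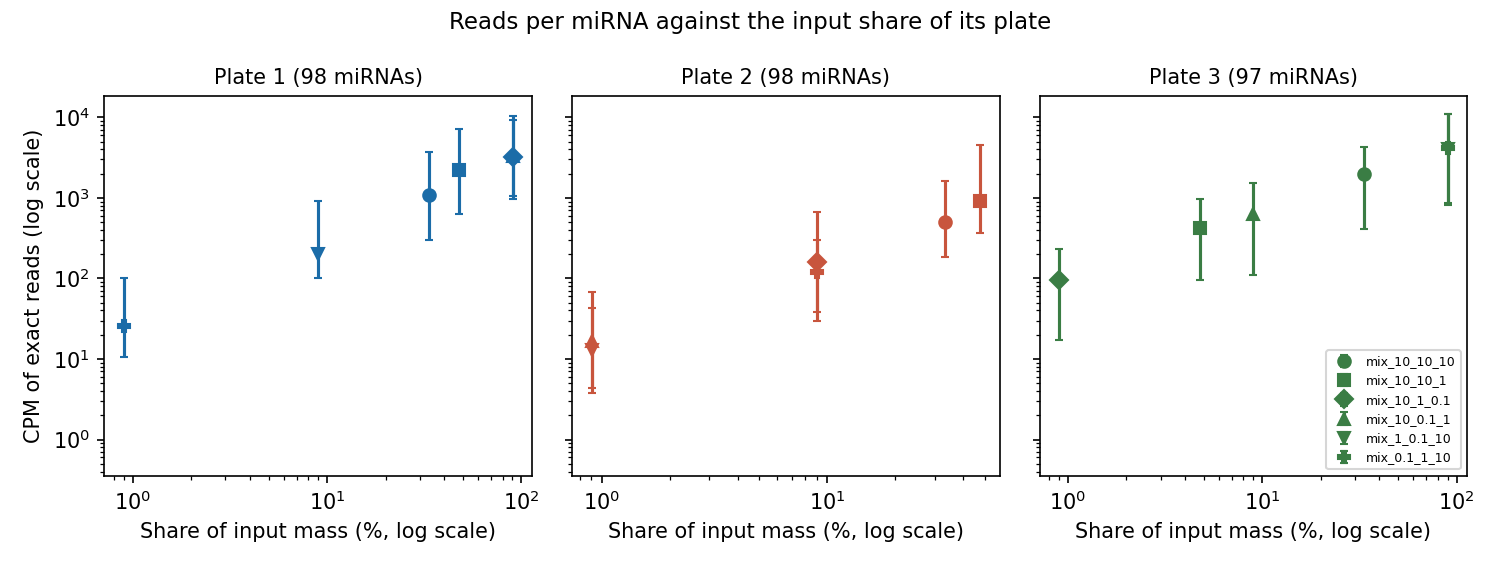
CPM of exact reads (log axis) against the share of input mass (percent, log axis) for each plate. Points are medians over the miRNAs with at least 1 read in a library, bars are quartiles over miRNAs, and symbols are the 6 libraries, of which mix_10_1_0.1 and mix_0.1_1_10 set the plates.

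Steep and shallow miRNAs differed by plate. On plate 1 the steepest was miR-3184-3p, at a slope of 3.29 (SE 0.51, adjusted p against 1 of 0.000149), followed by miR-136-3p at 1.74 (SE 0.22). This rests on its plate: alphabetical blocks of names put miR-3184-3p on plate 2, where its slope was 1.23 and no longer passed the test against 1, and with them 3 plate 1 miRNAs were steeper than 1 in place of 7. With all 6 libraries in the fit its slope on plate 1 was 1.02 and no longer passed the test against 0. The shallowest plate 1 miRNAs past the test against 1 were still above it, miR-184 at 1.56 and miR-146a-5p at 1.63. On plate 2, miR-30a-5p had a slope of 1.44 and miR-338-3p of 1.40. miR-107 and miR-103a-3p, whose hairpins lie within genes for pantothenate kinases, had slopes of -0.15 (SE 0.07) and -0.10 (SE 0.07). Their adjusted p against 1 was 0.000244 in edgeR, and neither passed the test against 0. Both were placed on plate 2 because their log2 ratios over the assigning pair, 2.82 and 2.30, lay nearer to the mass ratio of plate 2 than to that of plate 1. Name blocks put both on plate 1. On plate 3, miR-7-5p was steepest at 1.41 (SE 0.13), and miR-4433a-3p, at 0.04, and miR-4433b-3p, at 0.30, were shallowest. The call of miR-7-5p as steeper than 1 depended on the fit. On plate 3, 0 miRNAs were steeper than 1 in the DESeq2 Wald test, with all 6 libraries or with the other assigning pair.

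Some miRNAs left the line of their plate. The miRNAs of hairpins annotated on opposite strands of 1 locus, chosen after their values were seen, included miR-122-5p, miR-103a-3p and miR-486-5p. For these, plates were taken from alphabetical blocks of names, which put miR-122-5p and miR-103a-3p on plate 1, while the assigning pair put miR-103a-3p on plate 2. miR-122-5p relative to its predicted plate share was 12.95 times its mix_10_10_10 value in mix_10_1_0.1, 11.5 times in mix_0.1_1_10 and 0.767 times in mix_10_10_1. miR-103a-3p was 12.8 times in mix_0.1_1_10 and 0.432 times in mix_10_10_1.

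**Figure D2:**
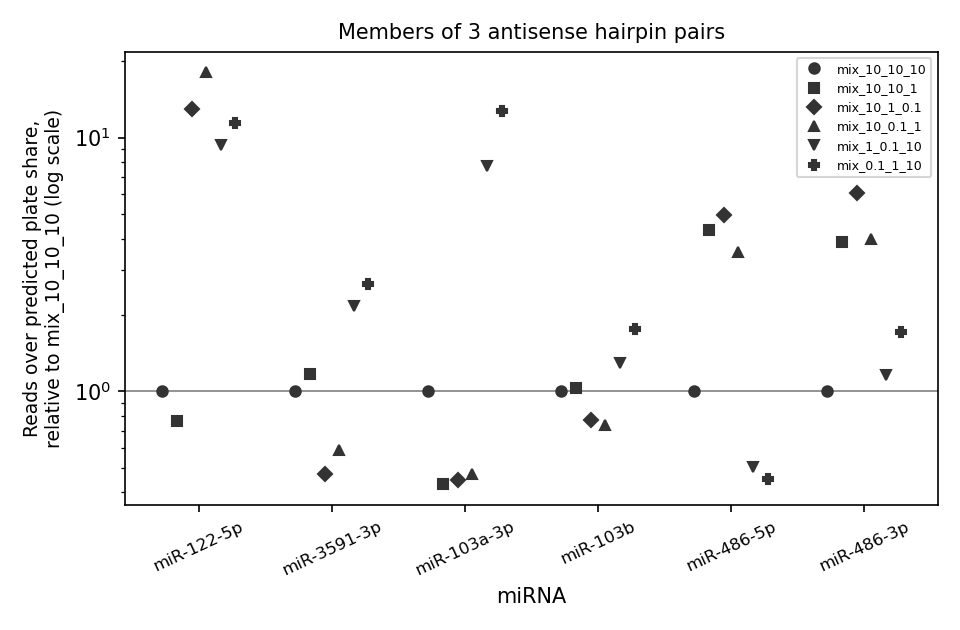
CPM over the predicted share of the plate by name block (log axis), relative to mix_10_10_10, for both members of 3 antisense hairpin pairs in the 6 libraries. Symbols are libraries, the line marks 1, and miR-122-5p reaches 18.1 in mix_10_0.1_1.

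Removing mass from plate 3 alone lowered plate 3 reads. Between mix_10_10_1 and mix_10_10_10, which differ in 1 against 10 ng of plate 3, the median log2 ratio was -2.33 on plate 3 (SD 0.69, 97 miRNAs), or 0.199 times. All 97 were lower. Plates 1 and 2, at 10 ng in both, had medians of 0.99 and 1.02. The mass shares alone give -2.81 for plate 3 and 0.51 for the others. The shares predicted from the reads per ng in mix_10_10_10 give -2.46 and 0.86. The plate 3 median lay at percentile 0 of random lists. These lists mix all 3 plates, and plates were set by response to mass, so this percentile adds no support. These values compare single libraries, with no replicate check, and TMM factors gave -0.91 for plate 3.

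Exchanging 10 and 1 ng between plates 1 and 3, at equal total mass, moved both plates in opposite directions. In mix_1_0.1_10 over mix_10_0.1_1 the median log2 ratio was -3.57 on plate 1 (SD 0.84), with 98 of 98 miRNAs lower, and 2.90 on plate 3 (SD 0.87), with 96 of 97 higher. The mass shares give -3.32 and 3.32, and the shares predicted from mix_10_10_10 give -3.74 and 2.90. For plate 2 they give 0 and -0.42. Plate 2, at 0.1 ng in both, had a median of -0.29 (SD 0.99), which is percentile 44.3 of random lists. Since these lists mix miRNAs of all 3 plates, this percentile does not test whether plate 2 stayed level.

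Plates did not take reads in proportion to mass. At equal mass in mix_10_10_10, plate 3 took 50.0% of exact reads, plate 1 34.97% (interval 34.95 to 34.99) and plate 2 14.8% (interval 14.8 to 14.9). At 10 ng against 1 and 0.1 ng, plate 1 took 93.2% of reads in mix_10_1_0.1 and plate 3 96.4% in mix_0.1_1_10. Plate 2 at 0.1 ng took 0.431% in mix_10_0.1_1 and 0.315% in mix_1_0.1_10, against a mass share of 0.901%. Plate 3 at 0.1 ng took 2.39% in mix_10_1_0.1 (interval 2.38 to 2.41). Reads per ng from mix_10_10_10 predicted the other 15 shares with a median absolute log2 error of 0.07. The largest excesses were plate 3 in mix_10_1_0.1, at 1.77 times its predicted 1.35%, and plate 1 in mix_0.1_1_10, at 1.30 times its predicted 0.674%.

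**Figure D3:**
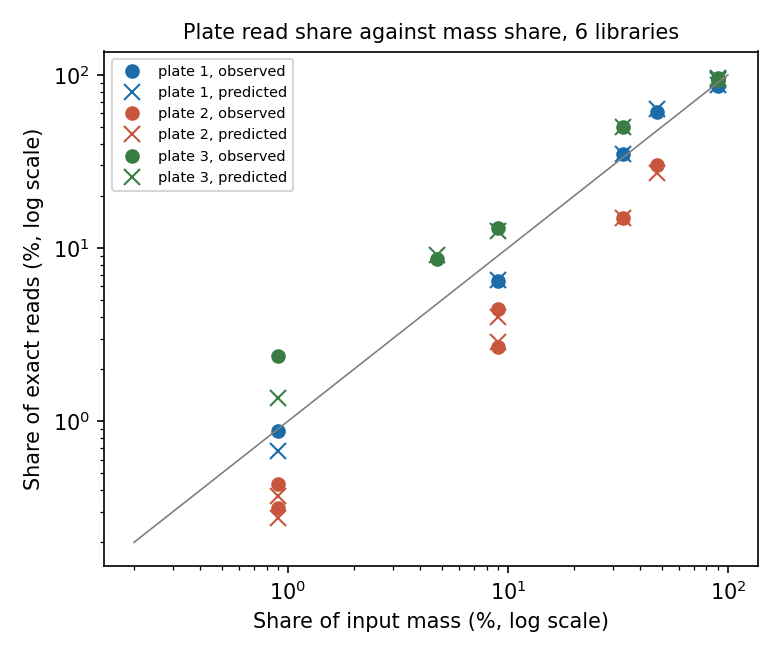
Share of exact reads against share of input mass, both in percent on log axes, for 3 plates in 6 libraries. Circles are observed, crosses are predicted from the reads per ng in mix_10_10_10, and the line marks equal shares. Plate 2 lies below the line in each library.

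Within a plate as set by reads, miRNAs differed widely in reads. The contents of the plates are not given in the sources used here, so names with few reads may not have been in the pool. In mix_10_10_10 the 90th percentile of reads was 94.0 times the 10th on plate 1 (bootstrap interval over miRNAs 42.02 to 243), 78.6 times on plate 2 and 97.2 times on plate 3. The plate 2 spread was 8959 times with a minimum of 1 read over the assigning pair and 29.2 times with 100. With up to 3 mismatches the spreads were 9094, 3965 and 6408 times on plates 1, 2 and 3. miR-378e had most reads, 815332, followed by miR-370-3p with 745821 and miR-490-3p with 708413, all on plate 3. miR-100-5p led plate 1 with 664251 reads, ahead of miR-148a-5p with 559546 and miR-1307-3p with 446450. Plate 2 was led by miR-30a-5p with 285820, miR-2355-3p with 216627 and miR-340-3p with 154670. The fewest reads were 17 for miR-181c-5p, 35 for miR-181d-5p and 117 for miR-106a-5p on plate 1. On plate 3 they were 90 for miR-6128, 140 for miR-378f and 160 for miR-378h. On plate 2, miR-378g had 35 reads, let-7i-5p 15 and miR-199a-3p 0. Under multiple assignment miR-199a-3p had 28661 reads in this library. Over the 6 libraries miR-181d-5p had 118 exact reads, and 257620 with up to 1 mismatch under multiple assignment. For miR-181c-5p these were 63 and 318. The order of miRNAs was similar between libraries, with Spearman correlations across miRNAs with mix_10_10_10 of 0.80 to 0.98 over 15 comparisons. miRNAs are not independent replicates.

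The lists fixed in advance followed the plates. Of 11 tested let-7 members, regulators of developmental timing, 10 rose with input share, also adjusted over the list alone, and 0 were off a slope of 1. let-7g-5p had a slope of 0.74 and let-7f-5p of 0.76, while let-7i-5p was at 0.07 with an adjusted p of 0.789 in edgeR. With 49 exact reads over all libraries, let-7i-5p was fitted as plate 2, while name blocks put it on plate 1. All 5 tested miR-30 members rose, and miR-30a-5p and miR-30e-3p (1.34) were steeper than 1. All 8 tested members of the miR-17 seed list rose. Lists took names of either arm, so this one includes miR-17-3p, miR-20a-3p and miR-93-3p, and its members need not share a seed. Of the miR-181 list, with 17 reads for miR-181c-5p and 35 for miR-181d-5p in mix_10_10_10, 4 of 4 rose. Of miR-15 and miR-16, 7 of 7 rose. So did 5 of 5 of miR-29, where miR-29b-3p was steeper than 1 at 1.38. All 4 miR-200 members, markers of epithelial cells, rose, and the 2 with most reads, miR-200c-3p and miR-200a-3p, had slopes of 1.10 and 1.21. The 4 members of the list of miR-34 and miR-449 and the 7 of the list of miR-10, miR-99, miR-100 and miR-125 rose, and the last group held 8.43% of exact reads in mix_10_10_10.

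Of the list of miR-302, miR-372 and miR-373, known from embryonic stem cells, 4 of 4 tested members rose, and miR-373-3p was shallower than 1 at 0.50 (SE 0.11). Of miR-103 and miR-107, 1 of 3 rose, miR-103b at 0.97. The others, miR-103a-3p and miR-107, were fitted as plate 2, while name blocks put them on plate 1. All 5 members of miR-25 and miR-92 and all 5 of miR-130 and miR-301 rose, as did 4 of 4 tested members of miR-148 and miR-152, where miR-148b-3p was steeper than 1 at 1.73. Of the muscle list 6 of 6 tested members rose. miR-1-3p was steeper than 1 at 1.66 and miR-499a-5p shallower at 0.54. The 5 brain list members rose, with miR-132-5p at 1.05 and miR-9-5p at 0.76. Of the blood and laboratory background list 11 of 13 rose. The exceptions were miR-486-5p, abundant in red blood cells, at -0.01 (SE 0.07), and miR-486-3p at 0.33 (SE 0.18). miR-486-5p was fitted as plate 2, while name blocks put it on plate 3. Counts adjusted over the list alone equalled those over all miRNAs in each list. No member of the C19MC or miR-548 lists could be tested: under mature names the first had 1 exact read and the second 0 over the 6 libraries. The name mir-548j, written as a hairpin and not counted in the list, had 3.

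Allowing mismatches added both reads and names. At least 10 exact reads were found for 297 miRNAs in mix_10_10_10 and for 281 in mix_10_1_0.1. In mix_10_10_10 the number was 316 with up to 1 mismatch, 370 with 2 and 997 with 3. Over the 6 libraries, 23 names under 10 exact reads reached 10 with 1 mismatch, 198 with 2 and 1715 with 3. These held 0.00150%, 0.0108% and 0.0684% of the reads. Among names under 10 exact reads, miR-500b-5p had most reads at 2 mismatches, 2331, followed by miR-1290 with 339 and miR-4440-5P with 314. Reads with 1 mismatch were 0.470 times the exact reads. miR-100-5p gained most, 1049029, and miR-7974 had the highest ratio of added to exact reads of the 10 that gained most, 0.916.

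Multiple assignment of exact reads changed 55 names, and the 10 with the largest gain took 91.4% of the gained reads. miR-378d gained 61759 reads, miR-378c 44264 and miR-378a-3p 40375. miR-500b-5p had 0 reads in single and 29659 in multiple assignment. Values of these names under single assignment are uncertain, since a read that fits several names is counted at 1 of them.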

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

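The tests on the share of plate 3 were chosen only after the results were seen, and the test on miR-199 was set before, except for how small gaps were judged. No biological explanation was tested, since the RNAs are synthetic and each mix is 1 library. Signals lay outside the measurements compared in the report. Reads of the full 50 nt, in which no adapter was removed, made up 6.35% of reads in mix_10_10_10, 6.16% in mix_10_10_1, 5.94% in mix_10_1_0.1, 6.24% in mix_10_0.1_1, 6.16% in mix_1_0.1_10 and 6.91% in mix_0.1_1_10. Reads that matched no human miRNA with up to 3 mismatches made up 19.3%, 19.4%, 18.1%, 18.9%, 16.6% and 19.2% in the same order.

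miR-199b-3p, which has no plate, had 28662 exact reads in mix_10_10_10 and 0 in each of the other 5 libraries, while miR-199a-3p had 0 there and 13693 in mix_10_10_1. If 1 sequence were counted under either name, multiple assignment would give both names equal reads, set in advance as exact equality with their sum in all 6 libraries. That held in 4. In the other 2 the names differed by few reads, 28661 against 28662 in mix_10_10_10 and 13693 against 13691 in mix_10_10_1. Exact equality was not met. The rule allowed no read to differ, and nothing here gives a spread for gaps of 1 and 2 reads. The explanation stays open.

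Plate 3 took 1.77 times its predicted share in mix_10_1_0.1. The prediction did not depend on the reference library alone, since the highest of 5 predictions was 1.41% against 2.39% observed. Reads misassigned between libraries may have added to it: the excess needs 0.168% to 0.227% of the reads of the other libraries. This test is the third form tried. Read first over the other 3 plates at 0.1 ng together, whose needed rates ran from -0.0207% to 0.466%, it covered that rate. Read per plate, 2 overlapped it and plate 1 in mix_0.1_1_10, at 0.0361% to 0.0887%, did not, so a single rate stays open. A rate of its own for this library and more plate 3 RNA than stated cannot be told apart. The 0% of plate 3 miRNAs below the level the first needs is what both predict, and the median log2 ratio above the corrected mass ratio by 0.60 (SD over miRNAs 0.78) restates the excess and decides nothing.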

How the results depend on the processing

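The predicted-share covariate, the plates by name blocks, the fit without antisense members, the summed miR-199 reads and the DESeq2 Wald test against a slope of 1 were chosen after seeing the data. Of 870 alternatives, 150 kept a main result, 9 weakened, 11 strengthened and 18 moved it. A named slope was kept in 611, weaker in 22, stronger in 30 and reversed in 19. No main result was counted as reversed, but plate medians changed side of 1. Plate 1 went from 1.13 to 0.14 with TMM factors, and plate 3 from 0.83 to 1.51. Those factors take most miRNAs as level between libraries, which the dilution of whole plates breaks by design. With TMM factors 174 miRNAs rose and 108 were off a slope of 1, median slopes were 0.14, 0.76 and 1.51, and the plate 3 fold was -0.91. With DESeq2 size factors the values were 171, 22, 0.66, 0.63 and 1.30. The count off 1 was 2 with the other assigning pair, 59 with all 6 libraries, 5 on log2 ng, 145 with up to 3 mismatches (plate 2 median 0.38) and 8 with the predicted share, which comes from a library in the fit. Leave-one-out fits of all libraries gave 28 to 54 off 1, 284 to 287 rising, and medians of 1.02 to 1.11, 1.00 to 1.12 and 0.80 to 0.85; the 54 came without mix_10_10_10. The median absolute log2 of read over mass share was 0.56 and moved to 0.563 with 1 mismatch, 0.549 with 3, 0.563 with multiple assignment and 0.472 with the other pair. With up to 3 mismatches 997 miRNAs were detected in mix_10_10_10. Names gained at 1, 2 and 3 mismatches were 387, 2754 and 4578 at 1 read, 10, 18 and 71 at 100 reads, and 71, 740 and 4613 with multiple assignment. The spread was 9094, 3965 and 6408 for plates 1, 2 and 3 with up to 3 mismatches, 1628 for plate 3 with 2, and 8959 and 29.2 for plate 2 at minimums of 1 and 100 reads. The cause was not tested.

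Slopes that changed sign were near 0 in the main analysis except those of miR-378h (0.73) and miR-6128 (1.01), which turned to -0.12 and -0.13 with 3 mismatches. For miR-378g they were -0.0037 with all 6 libraries, -0.42 with TMM, -0.51 with DESeq2 size factors, -0.12, -0.15 and -0.10 with 1 to 3 mismatches, -0.033 in DESeq2 and -0.011 with the predicted share, and -0.18 to 0.18 leaving out libraries. For let-7i-5p they were -0.043 with the other pair, -0.060 with TMM, -0.32 with DESeq2 size factors and -0.028 to 0.25 leaving out libraries. miR-107 was at 0.078 with name blocks and miR-103a-3p at 0.12 with the other pair. The cause was not tested. No paired analysis was possible because each mix is 1 library. Low depth limits the 0.1 ng plates, where the floor of 3 reads is up to 0.877 CPM.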

Other observations

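The tests of base pairing, of low read numbers and of the wrong plate were chosen after the values were seen. The test of shared reads was set before. Annotated hairpins that overlap on opposite strands by at least 30 bp gave 7 pairs with both miRNAs on a plate. MIR122 (GRCh38 chromosome 18, 58451074 to 58451158) overlaps MIR3591 (58451080 to 58451152), both outside protein-coding genes. miR-122-5p, the most abundant miRNA of liver, had 111 and 155 CPM in mix_10_10_10 and mix_10_10_1, where the plate of miR-3591-3p was at 10 ng. It had 3880 and 5002 in mix_10_1_0.1 and mix_10_0.1_1, with its own plate at 10 ng throughout. With its own plate at 1 ng in mix_1_0.1_10 and 0.1 ng in mix_0.1_1_10, it was 9.36 and 11.5 times its mix_10_10_10 value, relative to the predicted share. miR-103a-3p ran from 35.9 to 211 CPM over a 100-fold range of plate mass. MIR103A2 (chromosome 20, 3917494 to 3917571) lies within PANK2 and overlaps MIR103B2. miR-486-5p ran from 18.998 to 142.8 CPM. MIR486-1 (chromosome 8, 41660441 to 41660508) lies within ANK1 and overlaps MIR486-2.

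Over the 14 members the median SD of the deviation from the plate's profile was 0.94 on the log2 scale, against 0.40 over all miRNAs, at percentile 100 of 10000 random lists. Members differed: 7 lay above the 90th percentile of all miRNAs, while miR-451b lay at 9.56, miR-103b at 31.1 and miR-451a at 52.6. Plates are here the alphabetical blocks of names, which differ from the plates set by reads for miR-103a-3p, miR-486-5p and miR-3184-3p. By these blocks, the 8 members whose partner shares their plate had higher relative reads below 10 ng than at 10 ng in 8 cases, with a median difference of 1.54. Of the 6 members with the partner on another plate, 5 were lower where the partner had more mass. For miR-122-5p that log2 difference was only -0.18. In mix_0.1_1_10, where the plate of its partner had more mass than its own, it was still 11.5 times its mix_10_10_10 value. Shared reads (median gain by multiple assignment 0%) were excluded by their test. The counting SD was 0.0879 times the observed SD in the median member, below a cutoff set after the values were seen. It covers counting error only. On another plate 0 of 14 members had a lower SD (smallest rise 0.63), in the second form tried of that test. These values argue against low read numbers and a wrong plate but do not exclude them. Base pairing between complementary synthetic miRNAs may explain the pattern but stays open. Members of this list prompted the idea, so their percentile of 100 and the counts of direction above restate what was seen and decide nothing, and the mature sequences were not used here.

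The series describes random placement on plates, yet the plates followed the order of names. Cut into 3 alphabetical blocks, the names differed from the plate set by reads for 6 of 293 miRNAs, and the lowest of 10000 random orders was 157 differences. The 6 were let-7i-5p, miR-103a-3p, miR-107, miR-3184-3p, miR-378g and miR-486-5p. Outside the antisense pairs, miR-200a-3p at 10 ng of its plate had 2504 CPM in mix_10_10_10 and 18804 in mix_10_10_1. Relative to the predicted share of its plate, the mix_10_10_1 value was 4.12 times that in mix_10_10_10. Reads of 24 nt were 6.06% of reads in mix_1_0.1_10 and 1.15% in mix_10_1_0.1.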
